A study of Homo sapiens with 2 samples.

How the data were processed

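Poly-A messenger RNA from HepG2 cells with ectopic wild-type or Y78A ENL was reverse transcribed with random hexamers and sequenced, per the labels' protocols. Each group had 1 library. The authors deposited a table of raw read counts per gene and a table of FPKM values (fragments scaled by gene length and library total) for the same genes and libraries. Per the submitters' processing notes, HTSeq 0.6.1, edgeR 3.055 and the genome build hg19 were used, with no role given for each. The aligner, the annotation and whether counting used strand are not given in the sources used here. The coordinates in the tables are not those of hg19: of 55298 gene identifiers found in the GENCODE 29 annotation of GRCh38, 51496 had the identical chromosome, start and end and 99.9% overlapped the same gene. Coordinates are therefore given as in the tables and named as GRCh38. In the deposited FPKM table each value equals the count divided by the gene length and by a library total of 15159248 for wild type and 15975511 for Y78A, which differ from the sums of the counts (15271670 and 15694520). The counts were used for all main results and the FPKM values as an alternative.

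The table has 63094 rows. Of these, 337 are unannotated loci without a gene name, which held 0.287% of the counts in the wild-type library and 0.316% in the Y78A library. They were left out of library sizes and comparisons, which used the other 62757 rows. Gene lengths are those of the table. Older symbols were matched through a table of gene names. A total of 1335 symbols are listed at more than 1 locus, largely alternate sequences of the assembly, so reads of such genes can be split between entries. Close paralogs share the same limit, and without known strand use overlapping and antisense genes cannot be told apart.

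Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), to effective library sizes of 14981068 and 15902591, and expressed as CPM. The log2 ratio of Y78A over wild type was computed with a prior count of 2. Genes with a mean of at least 1 CPM were kept, and those with a ratio of at least 2-fold were counted, a size rule and not a test. Because each group has 1 library, no spread between replicates, p-value or standard error could be estimated. For each gene the exact 95% Clopper-Pearson interval of the share of its counts that fell in the Y78A library was turned into an interval of the ratio. PCR reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. Intervals widen as counts get lower, so the counts themselves are given for low genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 were used.

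Before the data were examined, 33 gene lists of pathways and 5 of markers of other cells were fixed, and some genes belong to more than 1 list. For each list with at least 4 measured members, the median log2 ratio was ranked among 10000 random lists of the same size drawn from protein-coding genes (with non-coding genes added for lists that hold them) in 20 bins of mean expression. A list stood apart below the 2.5th or above the 97.5th percentile, as a description of these libraries. The genes named were also fixed by rule: MLLT1 and MYC, the 12 protein-coding genes with the highest and the 12 with the lowest cautious log2 ratio (the interval bound nearest 0), up to 4 members of each list with the largest absolute log2 ratio, and the 4 most abundant coding genes of each library. Not every gene that this rule takes is reported here. A ranking over symbols at 1 locus was added after the first one proved to be filled by symbols at several loci.

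The alternatives fixed in advance were total-count, DESeq2 1.42.0 and upper quartile scaling, TMM without the 100 most abundant genes, no filter or a mean of at least 5 CPM, a prior count of 0.5, protein-coding genes alone, a 1.5-fold rule, the 2-fold rule on the cautious ratio, removal of a trend with gene length or with abundance, thinning of the deeper library, and log2(FPKM + 1) or log2(FPKM + 0.1), which understates the ratio of low genes. After the data had been seen, alternatives were added for GC content: removal of a lowess trend (span 0.3) of the log2 ratio on the GC content of the longest GENCODE 29 transcript, alone or with length, and random lists matched in 5 bins of expression and 4 of GC content. A GC value was found for 98.1% of measured genes. Restriction to symbols at 1 locus, with and without the GC trend, was added too.

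The procedure was tested on simulated Poisson counts for the real genes at the real library sizes, for the comparison of Y78A with wild type. Without a GC trend, 98.0% of 99 genes changed by a log2 ratio of 1.5 and 100% of 100 genes changed by 2.5 were found at least 2-fold apart in the right direction, as were 0.19% of 13154 unchanged genes in either direction, and 95.6% of 13393 counting intervals held the true ratio. With a GC trend simulated and left in, 94.9% of 99 genes changed by 1.5 and 100% of 100 genes changed by 2.5 were found, and 0.494% of 13152 unchanged genes were at least 2-fold apart. A simulated GC slope of −0.3 per 10 percentage points was estimated at −0.296 over 12902 genes and at 0.000723 after its removal. The simulation held no variation between cultures or library preparations. Its shares therefore cover counting error and the simulated trend only, and are not error rates for the real libraries.

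The test of counting error at symbols with more than 1 locus took 3 forms. The first ran only on genes already 2-fold apart and so decided nothing. The second compared all such genes with genes at 1 locus, whose differences are not counting error alone, and was left undecided. The one reported compares them with exact binomial counting at equal levels.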

Results

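Messenger RNA was sequenced from HepG2 cells, a human hepatoma line that keeps the expression of many liver genes. The cells ectopically expressed either wild-type ENL or ENL with the Y78A substitution. ENL, the product of MLLT1, is a chromatin reader that works with transcription elongation complexes. Its YEATS domain, where the substituted tyrosine lies, binds acylated lysines of histones. The series was concerned with the reading of histone β-hydroxybutyrylation by ENL. Its comparison asks which transcripts differ between cells that ectopically express either form of the protein. Whether the cells' own ENL remained was not examined here, and no library without an ENL construct was available for comparison. Each group had 1 library. Counts assigned to named genes totalled 15227833 in the wild-type library and 15644892 in the Y78A library, spread over 22243 and 22812 genes with at least 1 count. A mean of at least 1 CPM (count scaled to library size) was reached by 13366 genes, of which 11553 were protein-coding. All genes of the mitochondrial genome together took 9.50% and 9.51% of the counts, and the 100 most abundant genes 25.9% and 26.5%. With 1 library per group no difference had a replicate check, so "higher" and "lower" compare these 2 libraries. Log2 ratios are Y78A over wild type, pairs of levels are given with wild type first, and each bracketed range is an exact 95% Clopper-Pearson interval that covers counting error only.

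The medians of hepatocyte secreted genes, of bile acid and drug metabolism and of acute phase genes were higher in the Y78A library than those of matched random lists, with members on both sides. The fibrinogen chain FGB was 2.19-fold higher and the drug-metabolising enzyme CYP3A5 had a log2 ratio of 1.62. The medians of MYC-responsive growth genes, ribosomal protein genes, p53 targets and NRF2 targets of oxidative defence were lower. MYC was 1.96-fold lower, the p53 target FDXR 2.42-fold lower, and the ribosome biogenesis factor BOP1 and the NRF2 target OSGIN1 each had a log2 ratio of −1.15. G6PC, the enzyme that releases free glucose in gluconeogenesis (6.29-fold), and IGFBP1, a secreted insulin-like growth factor binding protein (2.83-fold), were higher, although their list was inside the limits as measured. Of 34 gene lists fixed in advance with at least 4 measured members, 5 stood above and 6 below expression-matched random lists, where 1.7 would be outside these limits by chance if genes within a list moved independently. All 11 stayed outside the limits on the same side when a strong trend with transcript GC content, described below, was removed. With this trend removed, MYC was 1.71-fold and FDXR 1.76-fold lower, and the log2 ratios of BOP1 and OSGIN1 were −0.56 and −0.63.

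MLLT1 (ENSG00000130382, GRCh38 chromosome 19, 6212955 to 6279948, minus strand) had 643 counts, or 42.9 CPM, in the wild-type library and 408 counts, or 25.7 CPM, in the Y78A library. Its log2 ratio was −0.74 (−0.92 to −0.56), a 1.67-fold lower level. The longest MLLT1 transcript has a GC content of 63.4%, and after removal of the GC trend the log2 ratio was −0.22. MLLT1 ranked at the 63.8th percentile of measured genes with wild-type ENL and at the 52.3rd with Y78A. The construct's sequence was not used here, so it is not known whether these counts include its message, and they show neither the dose of ectopic ENL nor which form was carried. MYC, a growth-promoting transcription factor known to depend on ENL in leukaemia (ENSG00000136997, chromosome 8, 127735434 to 127741434, plus strand), had 2469 counts (165 CPM) with wild-type ENL and 1337 (84.1 CPM) with Y78A. Its log2 ratio was −0.97 (−1.07 to −0.87), and −0.78 after removal of the GC trend.

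In all, 322 genes were at least 2-fold higher and 385 at least 2-fold lower in the Y78A library, so that 45.5% of these genes were on the higher side. Upper quartile scaling, which shifts the median log2 ratio of all measured genes by 0.10, gave 449 and 275 (62.0% higher). Removal of the GC trend gave 355 and 169 (67.7% higher), of which 249 and 148 were shared with the genes first counted. Among 2143 abundant genes (mean of at least 100 CPM) the SD of the log2 ratio across genes was 0.34, and 0.25 with the GC trend removed, against a median half-width of the counting interval of 0.079. The 4 most abundant coding messages were the same in both libraries. Their log2 ratios were −0.09 for MT-CO1, 0.06 for the matrix protein gene FN1, 0.08 for ALB and 0.46 (0.45 to 0.46) for APOB. With the GC trend removed these were −0.11, −0.07, −0.08 and 0.36, so FN1 and ALB turned from above to below 0.

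**Figure D1:**
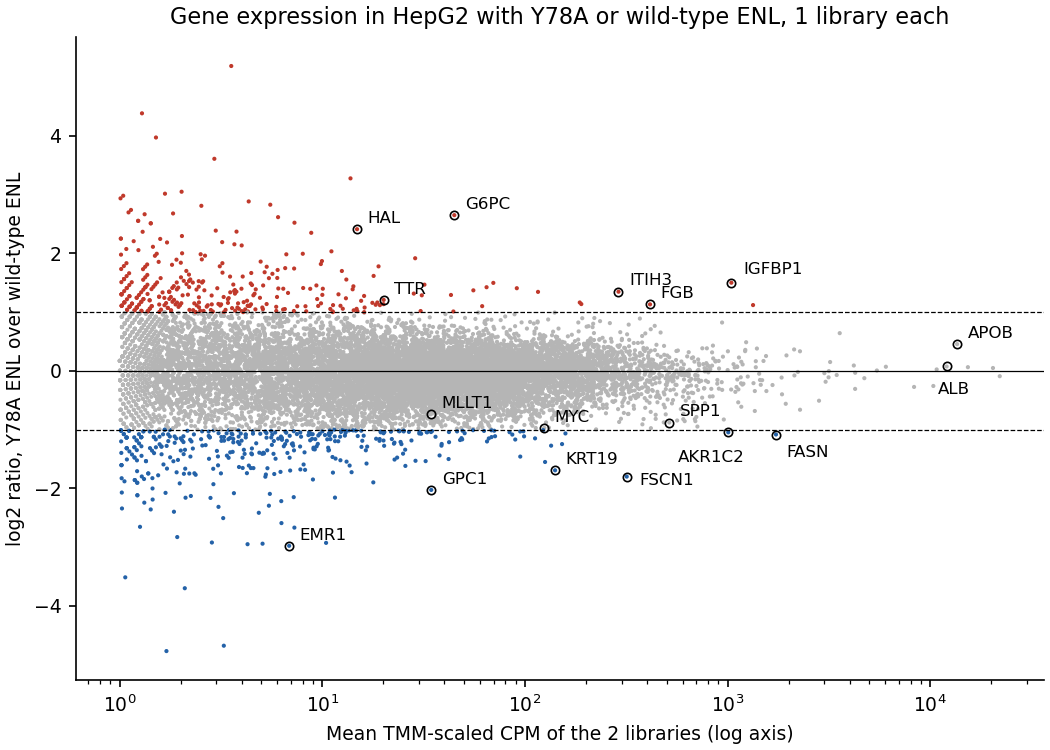
Each point is one of the 13366 genes with a mean of at least 1 CPM, with the mean TMM-scaled CPM of the 2 libraries on the horizontal log axis and the log2 ratio of Y78A over wild-type ENL on the vertical axis. Red points (322 genes) are at least 2-fold higher and blue points (385 genes) at least 2-fold lower in the Y78A library, dashed lines mark log2 ratios of 1 and −1, and circles mark named genes such as G6PC at 2.65 and FSCN1 at −1.80.

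The log2 ratio decreased with the GC content of the transcript. Over 11394 protein-coding genes the Spearman correlation across genes, which are not independent replicates, was −0.60. Over 1715 measured genes that are not protein-coding it was weaker, at −0.25. When the protein-coding genes were cut into 10 equal bins of GC content, the median log2 ratio was 0.24 in the lowest bin (median GC content 36.9%) and −0.58 in the highest (64.1%). Each gene list that stood apart is therefore given both as measured and with this trend removed, and the second value is called corrected.

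**Figure D2:**
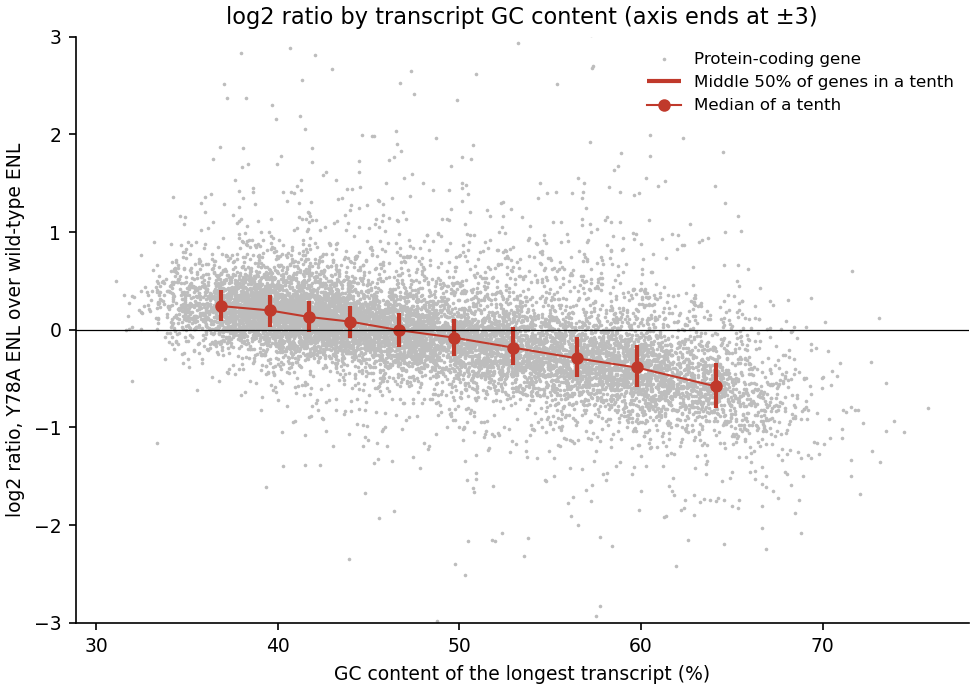
Each grey point is a protein-coding gene, placed by the GC content of its longest transcript in percent and by its log2 ratio of Y78A over wild-type ENL, and red circles and bars are the median and the middle 50% of each of 10 equal bins. The medians go from 0.24 at a GC content of 36.9% to −0.58 at 64.1%.

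Liver secretory genes stood above matched lists. Of 31 measured hepatocyte secreted and identity genes, 20 were higher and 11 lower in the Y78A library, with intervals that excluded 0 for 19 and 9. The list median was 0.25 (percentile 100 of 10000 random lists), and 0.31 corrected, and 4 members were at least 2-fold higher. TTR, which encodes the blood transport protein transthyretin, was at 12.1 and 28.1 CPM (1.21, 0.97 to 1.48). FGB was at 259.5 and 569.4 CPM (1.13, 1.08 to 1.19) and plasminogen, PLG, at 2.40 and 7.99 CPM (1.68, 1.19 to 2.31). GC, the gene of the vitamin D binding protein, had 8 and 72 counts (2.81, 2.03 to 4.35). Among 10 measured acute phase genes, which hepatocytes secrete in inflammation, 7 were higher and 3 lower. Their median was 0.24 (percentile 98.6), and 0.32 corrected. ITIH3 was at 163 and 416 CPM (1.35, 1.28 to 1.42), whereas HPX, the gene of the haem carrier hemopexin, had 26 and 11 counts (−1.18, −2.49 to −0.26).

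Of 18 measured genes of bile acid, drug and xenobiotic metabolism, 13 were higher and 5 lower, and 5 were at least 2-fold higher. Their median of 0.57 (percentile 100), or 0.48 corrected, was the highest of the lists with at least 4 measured members. The drug-metabolising enzyme CYP3A5 had 131 and 431 counts (1.62, 1.35 to 1.93) and the bile acid conjugating enzyme BAAT, listed at more than 1 locus, 32 and 93 (1.40, 0.86 to 2.08). The bile acid transporter subunit SLC51A had 71 and 202 counts (1.40, 1.03 to 1.83) and CYP2E1 had 15 and 45 (1.39, 0.63 to 2.45), and both overlap another measured gene.

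The 31 genes of glycolysis and the hypoxia response had a median of 0.22 (percentile 100), or 0.28 corrected, with 18 higher and 13 lower. The highest log2 ratios of its members were 0.88 for BNIP3L, 0.85 for the collagen prolyl hydroxylase P4HA1 and 0.84 for PDK1, which restrains the entry of pyruvate into the mitochondrial cycle. The lowest was −1.24 (−1.64 to −0.89) for the phosphofructokinase PFKP. The 15 measured NF-κB and inflammatory genes had a median of 0.25 (percentile 99.02), or 0.17 corrected (percentile 97.6), with 9 higher and 6 lower. The chemokine genes CCL20 (154 and 287 CPM, 0.90, 0.83 to 0.97), CXCL5 (18 and 59 counts, 1.53, 0.84 to 2.48) and CXCL2 (14 and 46 counts, 1.51, 0.74 to 2.61) were higher. With a mean of at least 5 CPM required, this list was at percentile 57.0.

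Growth genes stood below matched lists. All 40 MYC-responsive nucleolar and growth genes were measured. Of these 32 were lower and 8 higher, with intervals that excluded 0 for 29 and 4, and 3 were at least 2-fold lower. Their median was −0.35 (percentile 0), and −0.22 corrected. BOP1 was at 91.5 and 41.2 CPM (−1.15, −1.29 to −1.02, corrected −0.56). The nucleolar protein gene MYBBP1A was at 132 and 64.6 CPM (−1.03, −1.14 to −0.92, corrected −0.60) and the RNA exosome subunit gene EXOSC5 at 16.8 and 7.67 CPM (−1.12, −1.46 to −0.82, corrected −0.67).

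Of 72 measured cytosolic ribosomal protein genes 67 were lower and 5 higher, none by 2-fold, with a median of −0.32 (percentile 0), or −0.26 corrected. RPS2 was at 881 and 498.8 CPM (−0.82, −0.86 to −0.78, corrected −0.53). Of 35 genes of the G1/S transition and DNA replication 29 were lower and 6 higher. Their median was −0.27 (percentile 0.07), and −0.16 corrected. The replicative helicase subunit MCM5 (−0.82, −0.91 to −0.73, corrected −0.53) and the licensing factor CDT1 (−0.77, corrected −0.20) were farthest from 0. The 30 genes of G2/M and mitosis had a median of −0.11 (percentile 12.6), inside the limits, and −0.17 corrected (percentile 0.05), below them. CDC20, which activates the anaphase-promoting complex, was at −0.72 (−0.82 to −0.62, corrected −0.39).

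NRF2 targets, genes of antioxidant defence, had the lowest median of the lists, −0.60 (percentile 0), or −0.44 corrected. Of 19 measured members 17 were lower, each with an interval that excluded 0, and 3 were at least 2-fold lower. The sulfiredoxin gene SRXN1 had 78 and 15 counts (−2.31, −3.37 to −1.66) and OSGIN1 had 382 and 181 (−1.15, −1.43 to −0.90, corrected −0.63). The aldo-keto reductase AKR1C2 was at 1359 and 658 CPM (−1.05, −1.08 to −1.01, corrected −1.23), although it has close paralogs between which reads can be split.

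Of 23 measured p53 targets 19 were lower and 4 higher, with a median of −0.45 (percentile 0), or −0.31 corrected. FDXR, which encodes a mitochondrial reductase, was at 191 and 78.8 CPM (−1.27, −1.37 to −1.18, corrected −0.81). The proapoptotic gene BBC3 had 192 and 90 counts (−1.16, −1.56 to −0.81, corrected −0.40). Of 15 measured Wnt/β-catenin targets, a list that includes MYC, 12 were lower and 3 higher, with a median of −0.36 (percentile 0.17), or −0.19 corrected. The transcription factor gene SP5 was at 215 and 90.4 CPM (−1.25, −1.34 to −1.16, corrected −0.62). RNF43, a ubiquitin ligase that restrains Wnt receptors, was at 174.5 and 98.5 CPM (−0.82, corrected −0.73).

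**Figure D3:**
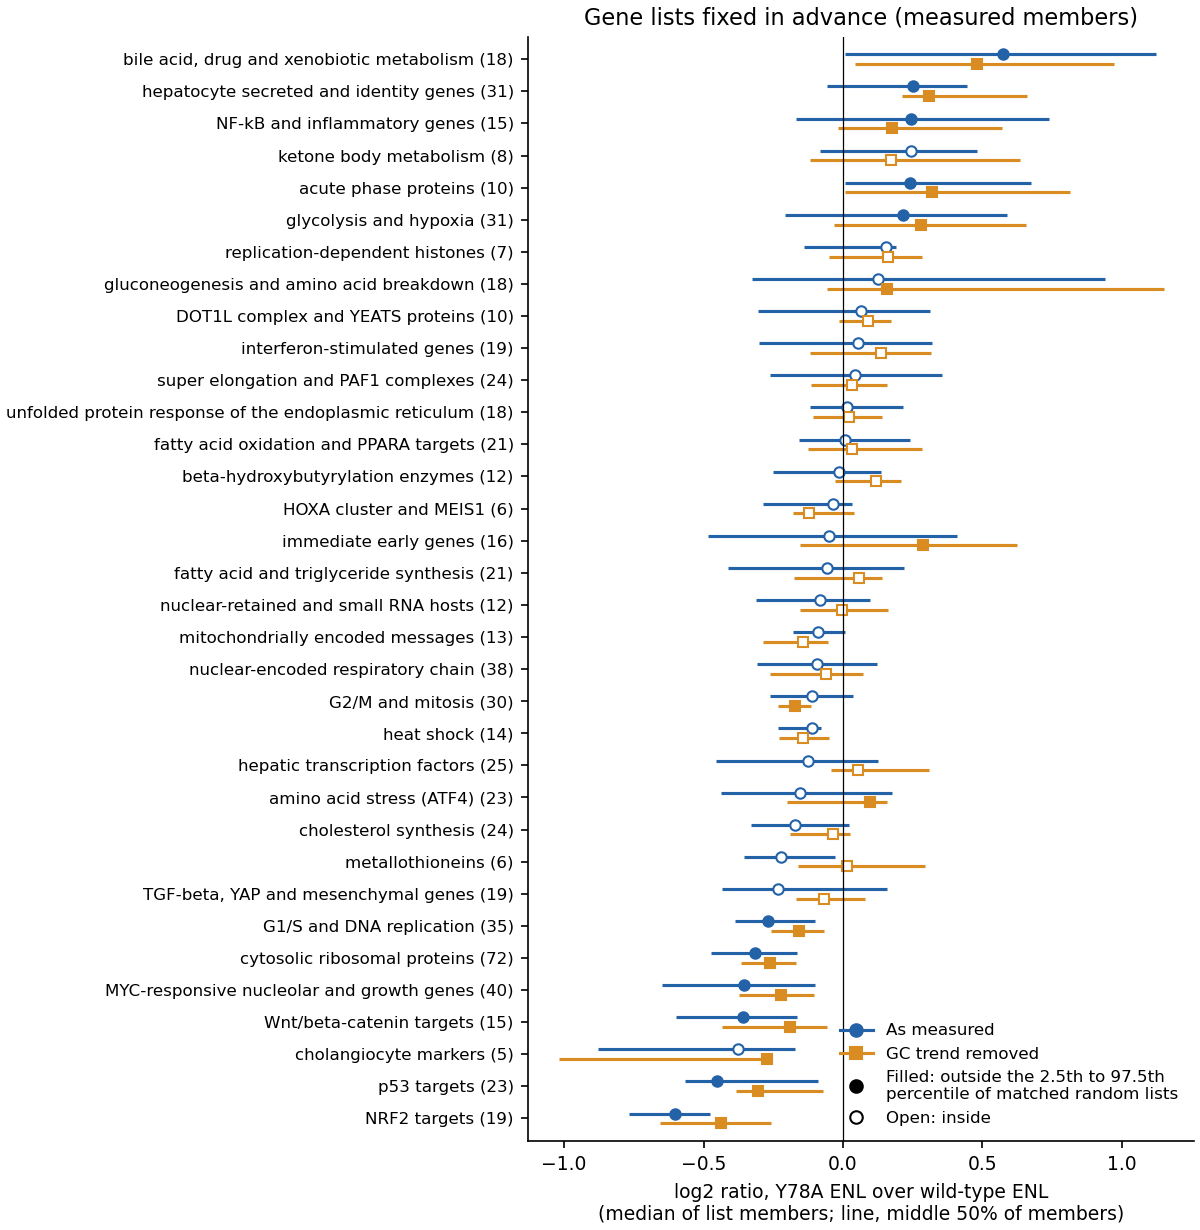
Each row is a gene list fixed in advance, with its number of measured members in brackets, and shows the median (symbol) and middle 50% (line) of the members' log2 ratios of Y78A over wild-type ENL, in blue as measured and in orange with the GC trend removed. Filled symbols lie outside the limits set by 10000 expression-matched random lists, and medians as measured go from −0.60 for NRF2 targets to 0.57 for bile acid, drug and xenobiotic metabolism.

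Lists tied to ENL itself were inside the limits as measured. The median was 0.04 (percentile 80.4) for 24 measured genes of the super elongation and PAF1 complexes and 0.06 (percentile 77.8) for 10 of the DOT1L complex and YEATS proteins. It was −0.01 (percentile 56.1) for 12 acetyltransferase and deacetylase genes, here called β-hydroxybutyrylation enzymes. They were listed as candidate writers or erasers of this mark, and not each is established as one. For 6 measured genes of the HOXA cluster and MEIS1 list, which ENL is known to maintain in leukaemia, it was −0.03 (percentile 55.6). Ketone body metabolism, with 8 measured genes, had a median of 0.24 (percentile 96.3). Its member BDH1, which interconverts acetoacetate and β-hydroxybutyrate and is listed at more than 1 locus, had 49 and 141 counts (1.40, 0.96 to 1.94). Within the elongation complexes NELFB (−0.64, corrected −0.08) and AFF1 (0.43, corrected 0.37) were among the members farthest from 0.

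Of 18 measured genes of gluconeogenesis and amino acid breakdown, 11 were higher and 7 lower and 5 were at least 2-fold higher. The median of 0.13 (percentile 93.7) was inside the limits, and the corrected one of 0.16 (percentile 98.7) above them. G6PC (ENSG00000131482, chromosome 17, 42900797 to 42913369) was at 12.2 and 77.5 CPM (2.65, 2.44 to 2.90). IGFBP1 (ENSG00000146678, chromosome 7, 45888357 to 45893668) was at 545 and 1544 CPM, with an interval of 1.47 to 1.54. The histidine-degrading enzyme HAL was at 4.61 and 25.1 CPM (2.41, 2.07 to 2.84), and PCK1, the entry enzyme of gluconeogenesis, had 8 and 39 counts (1.96, 1.08 to 3.51).

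Fatty acid oxidation and PPARA targets had a median of 0.01 (percentile 69.2, 21 genes). The fatty acid binding protein FABP1 was at 31.0 and 80.4 CPM (1.37, 1.22 to 1.53) and VNN1 had 9 and 55 counts (2.30). Fatty acid and triglyceride synthesis had a median of −0.06 (percentile 41.2, 21 genes; corrected 0.06, percentile 93). Fatty acid synthase, FASN, was at 2356 and 1112 CPM (−1.08, −1.11 to −1.06, corrected −0.49). Cholesterol synthesis had a median of −0.17 (percentile 4.20, 24 genes), with LSS at −0.71 (corrected −0.37). Hepatic transcription factors had a median of −0.12 (percentile 20.4, 25 genes; corrected 0.06, percentile 88.8), with CEBPA at −1.06 (corrected −0.45) and CREB3L3 at 0.99 (corrected 1.37).

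The remaining lists were inside the limits as measured. The median was −0.05 for 16 immediate early genes (percentile 50.7), −0.11 for 14 heat shock genes (percentile 21.8) and −0.16 for 23 amino acid stress genes under ATF4 (percentile 7.82). It was 0.01 for 18 genes of the unfolded protein response (percentile 72.0) and 0.05 for 19 interferon-stimulated genes (percentile 77.1). It was −0.22 for 6 metallothioneins (percentile 17.2) and −0.23 for 19 TGF-β, YAP and mesenchymal genes (percentile 3.71). The nuclear-encoded respiratory chain (38 genes, percentile 23.6) and the 13 mitochondrially encoded messages (percentile 33.6) each had a median of −0.09. The median was 0.15 for 7 replication-dependent histones (percentile 78.9) and −0.08 for 12 nuclear-retained RNAs and small RNA hosts (percentile 36.6). Corrected medians were above the limits for the immediate early genes (0.29, percentile 99.7), with DUSP5 at 1.24, and for the amino acid stress genes (0.10, percentile 97.8), but among random lists matched on expression and GC content both were inside them (percentiles 92.4 and 81.9). The long nuclear RNAs MALAT1 (55.1 and 105 CPM, 0.93, 0.81 to 1.05) and NEAT1 (150.1 and 253 CPM, 0.75, 0.68 to 0.83) were higher. Under upper quartile scaling the sign of the median turned for the β-hydroxybutyrylation enzymes, the HOXA cluster and MEIS1, immediate early genes, fatty acid and triglyceride synthesis, the respiratory chain, mitochondrially encoded messages and the nuclear-retained RNAs. With the GC trend removed it turned from below to above 0 for the β-hydroxybutyrylation enzymes (0.12, percentile 94.5), immediate early genes, amino acid stress genes, hepatic transcription factors, fatty acid and triglyceride synthesis and metallothioneins (0.01, percentile 52.3). Alternatives other than upper quartile scaling and those with the GC trend removed turned it for at most 4 lists each.

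Among single genes, 24 protein-coding entries were taken by their cautious ratio, the interval bound nearest 0. Of these, 17 belonged to symbols listed at more than 1 locus, mostly on alternate sequences of the assembly. VARS2, KIFC1 and CDK7 appeared on both sides. VARS2 had 96 and 2 counts at one alternate locus and 1 and 112 at another, and CDK7 had 14 and 123 counts on chromosome 5 and 136 and 17 on an alternate sequence. LPPR1 had 0 and 41 counts at one locus, and FAM120B 51 and 0. DNAJA3 (37 and 399 counts) and PCGF2 (278 and 37) are also listed at more than 1 locus. With counts summed over the loci of each symbol, the log2 ratio was 0.14 for VARS2, 0.01 for KIFC1 and −0.18 for CDK7. It stayed at 3.28 for DNAJA3 and −2.93 for PCGF2, whose other loci held no counts, so that summing could not change it. Reads that fit several loci may have been dropped before counting, so these entries remain uncertain.

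A ranking restricted to symbols at 1 locus was chosen after the data had been seen. Its higher side held G6PC, HAL, the epilepsy-linked secreted protein LGI1 (19 and 156 counts, 2.83, 2.26 to 3.72) and the mitochondrial carrier SLC25A27 (5 and 59 counts, 2.17 to 5.15). It also held the cytokine TNFSF14 (24 and 167 counts, 2.62, 2.09 to 3.39), the water and glycerol channel AQP3 (4 and 49 counts, 3.02, 2.08 to 5.46) and the metalloprotease MEP1A (31 and 199 counts, 2.52, 2.05 to 3.19). Unannotated loci beside TNFSF14, described under other observations, were higher to a similar degree. Its lower side held the adhesion receptor EMR1, also called ADGRE1 (184 and 23 counts, −2.98, −3.78 to −2.46), and the claudin CLDN11 (84 and 14 counts, −2.51). The actin-bundling protein gene FSCN1 was at 494 and 142 CPM (−1.80, −1.87 to −1.73, corrected −1.22). The heparan sulfate proteoglycan GPC1 was at 55.5 and 13.5 CPM (−2.03, −2.26 to −1.82, corrected −1.38). TUBA1A (−2.16), MAGEA3 (−2.08) and MAGEA6 (−2.16) were also lower, but have near-identical paralogs.

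Markers of other cells were also read. The 5 measured cholangiocyte markers, which hepatoma cells can also express, were all lower. Their median was −0.38 (percentile 2.54), just inside the limits, and −0.27 corrected (percentile 1.03), below them. The keratin gene KRT19 was at 215 and 66.5 CPM (−1.69, −1.80 to −1.59, corrected −1.23). SPP1, which encodes the secreted protein osteopontin, was at 668 and 363.5 CPM (−0.88, −0.93 to −0.83, corrected −1.02) and SOX9 at 265 and 204 CPM (−0.38). Too few markers of other types were measured for a percentile. Of fibroblasts and stellate cells 2 were measured, PDGFRB with 22 and 50 counts and ACTA2 with 522 and 432. Of endothelium 3 were measured, VWF with 9 and 34 counts, PECAM1 with 98 and 143 and ENG with 386 and 393. Of 10 leukocyte markers 8 were not measured, and LYZ and CD14 had 4846 and 8758 and 37 and 25 counts. Of 9 markers of an embryonic kidney line often used to package virus, 8 were not measured. The 1 measured, LIN28B, had 990 and 1314 counts. Which cells the LYZ and LIN28B messages come from was not tested.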

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

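The tests of reads shared between copies and of counting error at these genes were chosen after part of their results had been seen, and all alternatives that handle GC content were chosen after the data had been seen. The other tests were set before their results were seen.

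The rows that no comparison used also differed between the 2 libraries. Unannotated loci held 0.316% of the counts in the Y78A library (exact 95% interval 0.313% to 0.319%) against 0.287% (0.284% to 0.290%) in the wild-type library. Of 189 such loci with a mean of at least 1 CPM, 17 were at least 2-fold higher and 15 at least 2-fold lower in the Y78A library. These intervals cover counting error only. The loci were not set against the GC trend or against named genes of similar level. On chromosome 11, a locus at 78081121 to 78087539 that the authors' table matches to an endogenous retroviral HERV-H envelope had 245 counts with wild-type ENL and 45 with Y78A. On chromosome 5, a locus at 139503021 to 139514826 matched to a syncytin envelope had 186 and 536.

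The log2 ratio decreased with transcript GC content. A difference in GC bias between the libraries is a candidate explanation: within 72 cytosolic ribosomal protein genes, whose products cells need in fixed proportions, the slope was −0.27 per 10 percentage points (bootstrap 95% interval −0.33 to −0.21), close to −0.29 over all protein-coding genes. GC-rich promoters as the cause could be examined only through the 5' untranslated region, because promoter GC content was not measured. At fixed 5' untranslated region GC, the GC content of the rest of the transcript kept a partial Spearman correlation across genes of −0.58. That of 5' untranslated region GC at fixed GC of the rest was −0.09. These values argue against the 5' untranslated region as the whole source of the trend, but promoters stay open. Gene length is argued against by the partial correlation of GC at fixed gene length, also −0.58. The length of the transcript itself was not tested. A difference in ENL that itself acts by GC content stays open and was not tested, because each form of ENL has 1 library.

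Of the measured entries (gene identifiers) at symbols with more than 1 locus, 80 were at least 2-fold apart. A symbol can hold several entries. The 80 were 23.19% of 345 such entries (exact 95% interval 18.8% to 28.0%). Equal levels would give 0.497% by exact binomial counting at the same total counts, which argues against counting error as the whole cause. The interval treats entries as independent, although entries of 1 symbol can share reads, so it may be too narrow. Genes at 1 locus matched on mean expression gave 9.60%. Splitting of reads between copies, to which the opposite ratios of VARS2, KIFC1 and CDK7 point, could account for part. When the counts were summed over all loci of the symbol, 53 of the 80 entries (66.25%) stayed at least 2-fold apart, between the limits set for and against splitting. For some, such as DNAJA3 and PCGF2, the other loci held no counts, so summing could not change the ratio. This splitting cannot be told apart from real differences for this set, since reads that fit several loci equally well may have been dropped before counting. A biological difference between the forms of ENL at these genes was not tested.

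The medians of the hepatocyte lists were higher and those of growth genes, p53 and NRF2 targets lower in the Y78A library. The GC trend is argued against as the whole cause: among random lists matched on both expression and GC content, the median was at percentile 100 for hepatocyte secreted genes, 100 for bile acid and drug metabolism, 0.03 for MYC-responsive genes, 0 for ribosomal protein genes, 0 for NRF2 targets and 0 for p53 targets. The amount of ENL message stays open for the hepatocyte genes and cannot be told apart from the substitution, because the GC-corrected log2 ratio of MLLT1 was −0.22, it is not known whether MLLT1 counts include the construct, and 1 library per form ties dose to form. Differences between the cultures that have nothing to do with ENL, such as density or time of harvest, stay open for the same reason. The substitution itself stays open too and was not tested.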

How the results depend on the processing

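No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The alternatives for GC content and for symbols at 1 locus were chosen after the data had been seen. Among the alternatives that gave a value, no named gene that was at least 2-fold apart turned direction. Of 577 list percentiles under alternatives, 28 crossed the limits. Total-count, DESeq2 and upper quartile scaling, and TMM without the 100 most abundant genes, shift all log2 ratios by nearly the same amount. By construction, percentiles can hardly move under these, and all 34 lists kept their side of the limits there. Of the 11 lists that stood apart, 10 did so under every alternative, and the NF-κB list did not (percentile 57.0 with a mean of at least 5 CPM, where its median was −0.02, 97.3 with log2(FPKM + 1), 96.7 with log2(FPKM + 0.1), 97.2 with the GC trend removed at symbols with 1 locus). Lists inside the limits crossed them as follows. Without a filter, the super elongation and PAF1 complexes were at 98.3 and ketone body metabolism at 98.1, which was at 98.7 with log2(FPKM + 1). With the GC trend removed, with GC and length removed, and with the GC trend removed at symbols with 1 locus, G2/M and mitosis was at 0.05, 0.04 and 0.05, immediate early genes at 99.7, 99.8 and 99.8, gluconeogenesis at 98.7, 99.5 and 98.3, cholangiocyte markers at 1.03, 1.04 and 1.28, and amino acid stress, which was at 7.82 as measured and so reversed, in the first 2 of these at 97.8 and 99.3. The median of immediate early genes turned from −0.05 to 0.29 with the GC trend removed. Among GC-matched lists, G2/M was at 0.83, gluconeogenesis at 99.1, mitochondrially encoded messages at 1.39 and cholangiocyte markers at 0.82. The last were also at 2.23 with at least 5 CPM, 2.44 with the abundance trend removed and 2.48 with log2(FPKM + 1). The cause was not tested beyond the GC trend itself. The counts of genes at least 2-fold higher and lower moved by over 1.5 times without a filter (2049 and 2281), at 5 CPM (90 and 191), with log2(FPKM + 1) (64 and 98), with a 1.5-fold rule (1065 and 1542) and with the cautious ratio (96 and 107), each by construction, and on the lower side with the GC trend removed (169), with GC and length removed (168) and with GC removed at symbols with 1 locus (149). The log2 ratio of MLLT1 moved to −0.22 under each of these 3, and that of MYC to −0.78, −0.77 and −0.78, to −0.87 with upper quartile scaling and to −0.87 with length removed. Of 2956 values for the other named genes, 489 moved outside the counting interval, 287 of them under GC handling. Depth limits genes near 1 CPM, where about 15 counts stand behind each value.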

Other observations

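The list of other FOXO1 targets was written after G6PC, PCK1 and IGFBP1 had been seen to be higher, and before its median was computed. The value of its member SOD2 had been computed with the NF-κB list.

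TNFSF14 and C3 are neighbours on the minus strand of chromosome 19, with C3 at 6677704 to 6730562 and TNFSF14 at 6661253 to 6670588. C3, an abundant complement gene, was at 3165 CPM with wild-type ENL and 3159 with Y78A (log2 ratio −0.003, −0.02 to 0.02), whereas TNFSF14 had 24 and 167 counts (2.62, 2.09 to 3.39). An unannotated locus between them on the same strand, at 6671487 to 6676921, had 22 and 167 counts (2.73, 2.19 to 3.55), and one annotated on the plus strand, at 6670759 to 6674201, had 10 and 52 (2.09, 1.30 to 3.43). These loci were singled out after their values had been seen. It was not tested whether the counts at TNFSF14 come from transcripts of its own.

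G6PC, PCK1 and IGFBP1, which were higher in the Y78A library, are known targets of FOXO1, the transcription factor that insulin signalling keeps out of the nucleus. As a hypothesis, other FOXO1 targets may be higher as a group. Of 22 measured genes in such a list, 17 were higher and 5 lower, with intervals that excluded 0 for 13 and 5. The list had a median log2 ratio of 0.24, at percentile 99.95 of expression-matched lists and 99.98 of lists matched on expression and GC content. PIK3IP1, which restrains phosphoinositide 3-kinase, had 106 and 236 counts (1.05, 0.73 to 1.41), the cyclin CCNG2 301 and 566 (0.82, 0.62 to 1.03), the sterol transporter subunit ABCG5 238 and 404 (0.67, 0.44 to 0.91) and SOD2, which the NF-κB list also holds and which overlaps other measured genes, 5440 and 9089 (0.65, 0.61 to 0.70). Without SOD2 the median of the other 21 genes was 0.21, at percentiles 99.7 and 99.85 of the same kinds of lists. Many of the listed genes are also active in liver, and the hepatocyte list stood above matched lists as well, so the values are consistent with a wider difference in liver genes too. Nutrient or growth factor supply in the 2 cultures, which was not measured here, stays open.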
